A study of Gallus gallus with 9 samples.

How the data were processed

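RNA sequencing libraries from 9 samples of chicken embryo myoblasts were analysed from the deposited tables, 1 per sample, 3 each from cells just after serial plating (PM), in growth medium (GM) and after 4 days in differentiation medium (DM). Per the labels, total RNA was taken with Trizol and libraries followed standard Illumina protocols. HISAT, an aligner, and HTSeq, a read counter, are named in the submitters' processing notes. Their versions, the genome build, the annotation release and the use of strand are not given in the sources used here. Each deposited table lists, per gene, a raw read count, an FPKM value and a gene length, per the file headers. The counts are whole numbers as the authors deposited them. The FPKM values are the authors' own, and for 64.7% of genes they used the listed length. Coordinates are printed as the files list them, in a build that is not given, and symbols are those the files pair with their gene identifiers, given for 11078 of 24881 genes. With strand use not given, reads of overlapping or antisense genes cannot be told apart. Reads of close paralogs such as HBAA and HBAD may also be mixed, whatever the use of strand.

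Features without an Ensembl identifier were left out of the main tests. The PM tables hold 1069 of them, and the GM and DM tables hold 1710. For 0 of 1029 compared did the length implied by count and FPKM agree between tables (relative tolerance 0.001), against 18188 of 18188 Ensembl genes. The listed coordinates did agree, for 25950 of 25950 shared identifiers, Ensembl genes included. Whether an identifier of this kind stands for the same feature in PM and in the other groups is therefore not settled. Features without an Ensembl identifier took 1.58% to 2.12% of the reads. The GM and DM tables each hold 2 broken lines, which were dropped. The analysis used 24881 Ensembl genes per library and 15731818 to 27110310 of their reads. A count of 3 reads, the floor used for genes without reads, amounts to 0.111 to 0.191 CPM. Intervals and floors cover counting error only. Replicates of a group differed by far more than sampling noise (chi-square per gene 6.10 to 63.0), so none was counted as a duplicate.

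The design had been written for FPKM, with the count test named as the main test if the tables held counts, and they did. Genes kept by filterByExpr (14796) were normalised by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust) over all 9 samples without a block, and called at a Benjamini-Hochberg adjusted p below 0.05. The 29 gene lists, with 9 of them markers of other cell types, were fixed before the data were examined. They cover sarcomere, excitation-contraction coupling, neuromuscular junction, myoblast fusion, myogenic regulators, muscle energy metabolism, mitosis, DNA replication, cell cycle exit, ribosomal proteins, nuclear and mitochondrially encoded oxidative phosphorylation, glycolysis, cholesterol synthesis, unfolded protein and integrated stress, immediate early, interferon and proteolysis genes, growth factor and Notch signalling, and markers of fibroblasts, smooth muscle, endothelium, macrophages, erythroid, neural, tendon, adipocyte and epidermal cells. Lists were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 87 tests, and again with an estimated correlation. Genes to be named were also fixed by rule beforehand. Per comparison these were the 5 largest rises and 5 largest falls among called genes with a symbol, no overlap between replicates and at least 10 FPKM in the higher group. Per list they were up to 4 called members with the largest fold change and at least 5 FPKM, or up to 2 of the most abundant members where none was called. Always included were PAX7, MYF5, MYOD1, MYOG, MYF6, MEF2C, MYMK, CKM, DES, MKI67, CDKN1A, CDKN1C and MSTN. The files pair no tested gene with the symbols PAX7, CKM, MKI67 or CDKN1C, so these were not analysed here. Not every gene the rule names is printed.

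The edgeR and camera steps were tested on simulated counts with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Of 14796 genes simulated, the changed ones were drawn from those with better expression and were far fewer than the data call. Each gene had the same spread in all groups, so recovery in the data may differ. For GM versus PM, 49.3% of 1.5-fold, 95.5% of 2-fold and 98.5% of 4-fold changes were recovered, with 10 unchanged genes called. For DM versus GM the shares were 50.7%, 94.0% and 98.5%, with 13 unchanged genes called. Alternatives fixed beforehand were DESeq2 1.42.0, its size factors, no filter, an FPKM minimum of 5 in 3 samples, limma on log2(FPKM + 0.1) and on quantile-normalized log2(FPKM + 1), no trend, 6-sample fits, a replicate block, a 2-fold minimum and leaving out each sample. Removing the gene length trend per library (lowess, span 0.3) was added after seeing the data. The design had named limma on log2(FPKM + 1) as the main test for tables without counts. It was added as an alternative only after seeing the data. On the log2(FPKM + 0.1) scale the median of all genes in GM versus PM moved by 0.15.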

Results

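Gene expression was measured by RNA sequencing in primary myoblasts, the mononucleated muscle precursors that fuse into myotubes, from chicken embryo skeletal muscle. The 9 libraries fell into 3 groups of 3. PM libraries came from cells collected when serial plating, the step that enriches myoblasts, had just ended. GM libraries came from cells in growth medium with 15% fetal bovine serum, and DM libraries from cells after 4 days in differentiation medium with 2% horse serum. All were labelled passage 1. The tables held 16052542, 16689455 and 20981337 counted reads in PM replicates 1 to 3, 24584188, 23164541 and 27546527 in GM, and 23519295, 22887248 and 21893152 in DM. The labels do not say whether the replicates came from separate cultures or embryos, so the p-values measure only the spread between these samples. Of 24881 listed genes, 14796 had enough reads to be tested. Values after ± are SDs over 3 replicates throughout. Each SE is the absolute log2 fold change divided by the square root of edgeR's quasi-likelihood F statistic, and not an estimate made by the fit.

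The 3 groups were well separated. The first principal component of log2 CPM held 50.5% of the variance and ran from PM through GM to DM. The second held 36.0% and set GM apart from both other groups. Pearson correlations across genes were 0.983 to 0.992 between replicates and 0.901 to 0.938 between groups. Biological variation between replicates was 9.21% in PM, 17.1% in GM and 10.6% in DM. GM replicate 3 lay apart from the other GM libraries on the third component, where its score was -33.6 against 14.98 and 21.4.

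**Figure D1:**
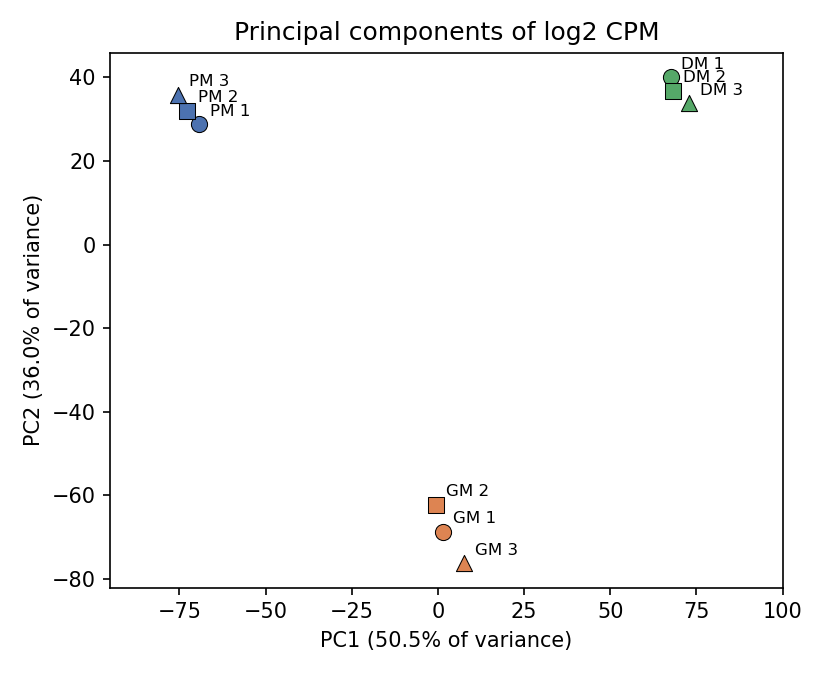
Principal components 1 and 2 (arbitrary units, share of variance on each axis) of log2 CPM for the 9 libraries, with colour for the group and symbol for the replicate. PM lies at the left, DM at the right and GM at the bottom, and PC1 and PC2 hold 50.5% and 36.0% of the variance.

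The GM versus PM comparison asked which genes differed between cultured cells and cells just after plating. Genes of the contractile apparatus were higher in GM. In the list of sarcomere genes, 36 rose and 4 fell of 43 measured, with a median log2 fold change of 2.16 (camera adjusted p = 3.77e-10, adjusted p = 0.605 with an estimated correlation). MYOM2, an M-band protein, rose from 1.35 ± 0.259 to 26.0 ± 13.9 FPKM (log2 fold change 4.15, SE 0.41, edgeR adjusted p = 4.28e-05). MYPN, a Z-disc protein, rose from 2.27 ± 0.631 to 37.8 ± 17.1 FPKM and KLHL31 rose from 3.22 ± 0.297 to 43.8 ± 18.3 FPKM. The intermediate filament gene DES (ENSGALG00000011306, chromosome 7, 22291852 to 22295615, minus strand) rose from 155 ± 3.66 to 811 ± 407 FPKM (log2 fold change 2.26, SE 0.32, edgeR adjusted p = 3.22e-04).

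Genes of excitation-contraction coupling and of the neuromuscular junction moved in the same direction. In the coupling list 16 rose and 1 fell of 20, and the median was 1.42 (camera adjusted p = 6.38e-05, adjusted p = 0.554 with an estimated correlation). The calcium channel genes CACNA2D1 and CACNA1S rose from 1.24 ± 0.237 to 10.7 ± 4.52 FPKM and from 0.807 ± 0.0714 to 5.12 ± 2.66 FPKM, and SRL, a sarcoplasmic reticulum protein, rose from 19.9 ± 0.966 to 143 ± 67.6 FPKM. In the neuromuscular junction list 13 rose and 1 fell of 20, with a median of 0.98 (camera adjusted p = 0.00204, adjusted p = 0.599 with an estimated correlation). The acetylcholine receptor subunits CHRND and CHRNG rose from 6.12 ± 1.07 to 45.1 ± 23.0 FPKM and from 7.47 ± 0.563 to 30.2 ± 16.01 FPKM, and ERBB3, a neuregulin receptor, rose from 0.779 ± 0.119 to 7.59 ± 4.11 FPKM. In GM replicate 3 the median level of these lists was the highest of all libraries, and its sarcomere list lay 1.07 log2 units above the mean of GM replicates 1 and 2.

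The myogenic regulatory factors, the transcription factors that commit cells to muscle, did not move together. MYF6 fell from 102 ± 3.89 to 44.0 ± 10.4 FPKM (log2 fold change -1.37, SE 0.17, edgeR adjusted p = 4.49e-05). MYOD1 (ENSGALG00000006216, chromosome 5, 12184436 to 12187655, plus strand) fell from 332 ± 11.7 to 254 ± 37.2 FPKM (log2 fold change -0.53, SE 0.11, edgeR adjusted p = 0.00154). MYF5 (ENSGALG00000028091, chromosome 1, 40002758 to 40003972, plus strand) fell from 406 ± 22.2 to 294 ± 94.7 FPKM (log2 fold change -0.62, SE 0.23, edgeR adjusted p = 0.0408). The MYF5 call was lost without PM replicate 1, 2 or 3 (edgeR adjusted p = 0.0664, 0.0891 and 0.1). It was also lost without the low-count filter and with PM and GM fitted alone (edgeR adjusted p = 0.0938 and 0.0582), and the log2 fold change was -0.39 without GM replicate 3. With the gene length trend removed, an alternative chosen after seeing the data, neither MYF5 nor MYOD1 passed (edgeR adjusted p = 0.378 and 0.0535). On quantile-normalized FPKM their log2 fold changes were -0.14 and -0.03 (limma adjusted p = 0.649 and 0.837). MYOG, which drives terminal differentiation (ENSGALG00000000172, chromosome 26, 968610 to 972124, minus strand), rose from 177 ± 8.53 to 367 ± 138 FPKM (log2 fold change 0.91, SE 0.23, edgeR adjusted p = 0.00776), and its log2 fold change was 0.53 without GM replicate 3. MEF2C, a cofactor of these regulators, rose from 9.10 ± 1.19 to 92.7 ± 50.1 FPKM (log2 fold change 3.22, SE 0.37, edgeR adjusted p = 1.06e-04). ID4, an inhibitor of such helix-loop-helix factors, fell from 968 ± 62.0 to 185 ± 10.97 FPKM, while EYA1 rose from 6.74 ± 1.15 to 29.3 ± 9.13 FPKM and SIX4 rose from 4.13 ± 0.785 to 17.3 ± 1.83 FPKM. The list of myogenic regulators as a whole was not called (10 rose and 8 fell of 19, camera adjusted p = 0.746). TMEM8C, the file name of the fusion factor myomaker, was 71.4 ± 1.52 FPKM in PM and 118 ± 45.6 FPKM in GM (edgeR adjusted p = 0.0533), and passed without GM replicate 1, 2 or 3 (edgeR adjusted p = 0.0316, 0.00887 and 0.0298), with a log2 fold change of 0.20 against 0.59 in the last case. The fusion list was not called (11 rose and 5 fell of 23, 12 and 5 adjusted over the list alone), although CAV3 rose from 30.3 ± 2.81 to 149.7 ± 81.3 FPKM and ITGA7 rose from 0.965 ± 0.304 to 8.69 ± 5.4998 FPKM, with a log2 fold change of 3.04, and 2.36 without GM replicate 3. MSTN, a repressor of muscle growth, rose from 3.73 ± 0.853 to 6.39 ± 1.64 FPKM, a call lost without PM replicate 3 or GM replicate 2 (edgeR adjusted p = 0.0657 and 0.0646). CDKN1A was 38.4 ± 1.92 FPKM in PM and 33.5 ± 7.59 FPKM in GM (edgeR adjusted p = 0.0958), and passed without GM replicate 3 (edgeR adjusted p = 0.00265).

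**Figure D2:**
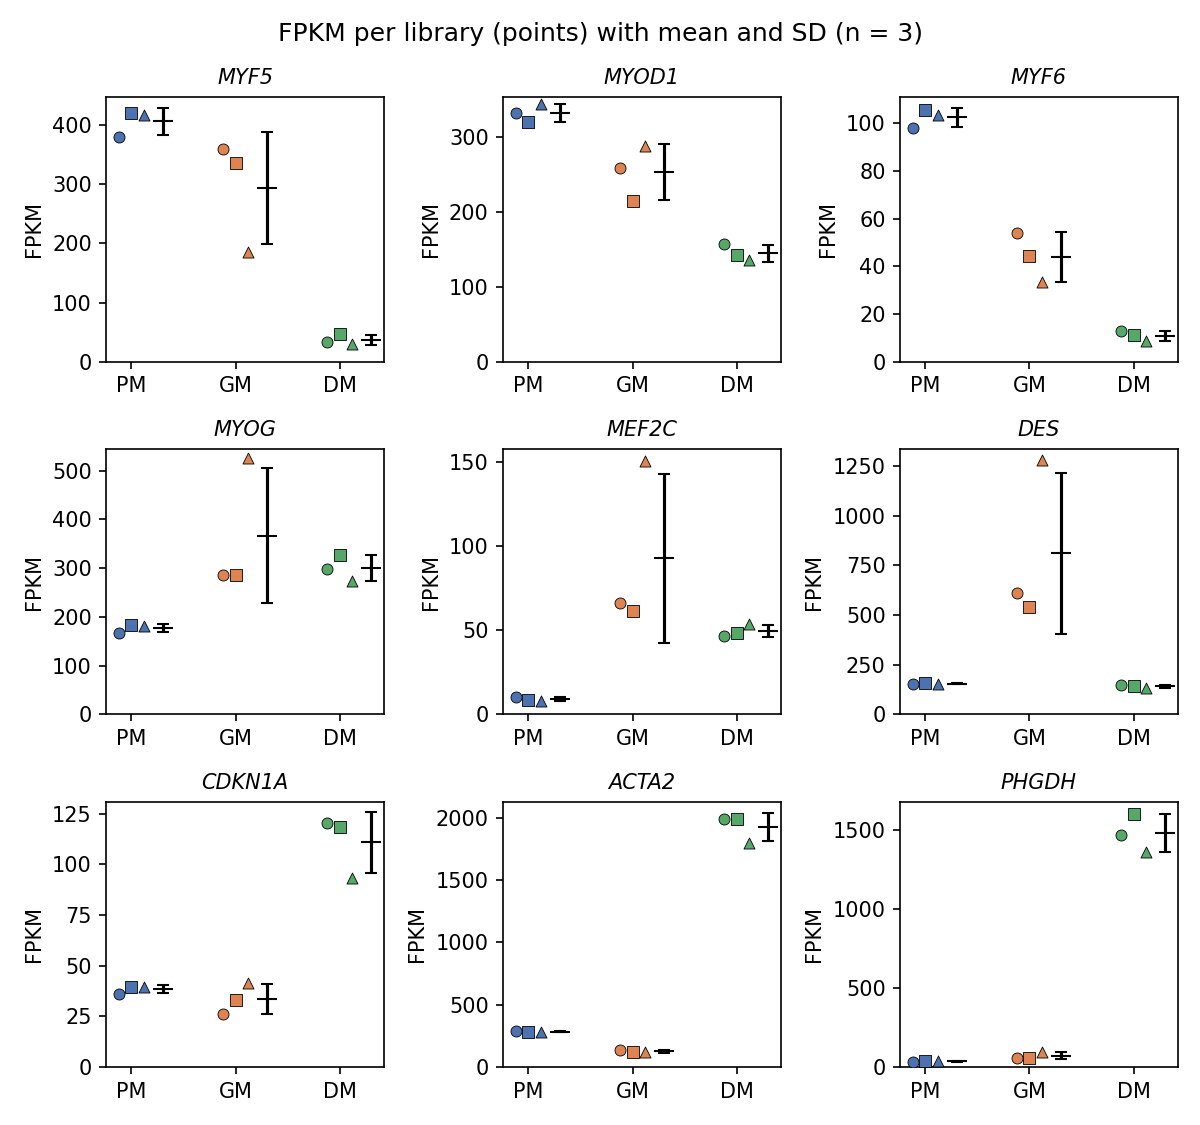
FPKM (vertical axes, from 0) of 9 genes in each library, with points for the replicates and a bar for the mean ± SD of 3. MYF5 averaged 406 ± 22.2, 294 ± 94.7 and 37.0 ± 8.65 FPKM in PM, GM and DM, DES was highest in GM, and ACTA2 and PHGDH were highest in DM.

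Ribosomal protein genes and nuclear genes of oxidative phosphorylation were lower in GM. In the ribosomal list 0 rose and 56 fell of 58, with a median of -0.76 (camera adjusted p = 1.18e-14, adjusted p = 0.554 with an estimated correlation). RPL38 fell from 1299.7 ± 61.8 to 448 ± 40.3 FPKM and RPS23 fell from 3819 ± 186 to 1797 ± 166 FPKM. In the oxidative phosphorylation list 0 rose and 41 fell of 44, with a median of -0.67 (camera adjusted p = 3.50e-11, adjusted p = 0.554 with an estimated correlation), and COX6B1 fell from 1012 ± 29.8 to 313 ± 37.9 FPKM. Genes encoded on the mitochondrial genome went the other way (7 rose and 1 fell of 13, 6 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.0498, adjusted p = 0.755 with an estimated correlation). ND6 rose from 234 ± 26.5 to 1042 ± 193 FPKM and ND5 rose from 809.7 ± 47.5 to 2099 ± 249 FPKM. That call was lost without PM replicate 1 or 2 or GM replicate 1 or 3 (camera adjusted p = 0.0666, 0.0602, 0.0532 and 0.165), with DESeq2 size factors and with an FPKM minimum of 5 (camera adjusted p = 0.0501 and 0.0588), and on log2(FPKM + 0.1) (camera adjusted p = 0.0549). Mitochondrial genes took 2.96% to 3.32% of the reads in PM and 3.75% to 4.84% in GM. Ribosomal and oxidative phosphorylation genes are short, and fold changes were higher for longer genes here. The median log2 fold change was -0.73 in the shortest and 0.61 in the longest of 8 length bins of well-expressed genes. With this trend removed, an alternative chosen after seeing the data, the medians were -0.44 for ribosomal genes, -0.36 for oxidative phosphorylation and 0.53 for the neuromuscular junction. That of mitochondrially encoded genes was 0.69, with the call kept (camera adjusted p = 7.59e-04). The ribosomal call was lost on quantile-normalized FPKM, where the median was -0.13 (camera adjusted p = 0.0784).

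**Figure D3:**
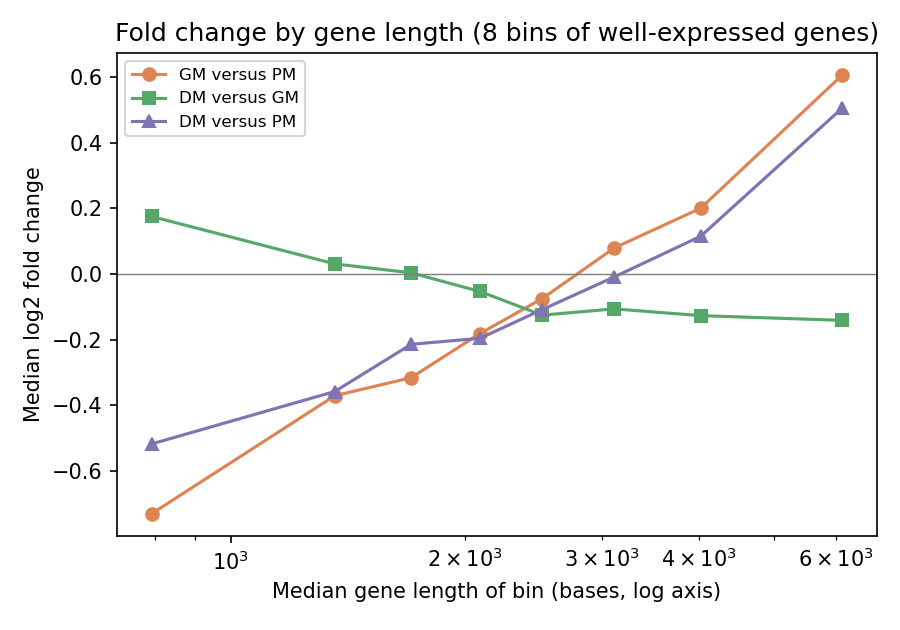
Median log2 fold change (vertical axis) in 8 bins of gene length (horizontal log axis, bases) for the 3 comparisons, over genes with a mean log2 CPM above 5. The line for GM versus PM runs from -0.73 to 0.61 and that for DM versus PM from -0.52 to 0.51, while DM versus GM stays between -0.14 and 0.18.

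Markers of immune cells were lower in GM. In the macrophage and leukocyte list 2 rose and 19 fell of 22, with a median of -1.60 (camera adjusted p = 7.77e-06, adjusted p = 0.554 with an estimated correlation). LY86 fell from 39.2 ± 0.671 to 1.51 ± 0.944 FPKM (log2 fold change -4.81, SE 0.34, edgeR adjusted p = 2.48e-06). The complement genes C1QA and C1QC fell from 143 ± 8.72 to 16.7 ± 10.5 FPKM and from 167 ± 8.21 to 15.0 ± 9.15 FPKM. Without GM replicate 3 the log2 fold changes of LY86, C1QA and C1QC were -5.50, -3.91 and -4.27. The chemokine genes CCL4 and CCL5 fell from 251 ± 5.33 to 30.005 ± 5.62 FPKM and from 18.0 ± 4.28 to 1.08 ± 0.408 FPKM. Interferon response genes fell with them (0 rose and 18 fell of 20), with a median of -1.02 (camera adjusted p = 1.50e-04, adjusted p = 0.570 with an estimated correlation), and B2M fell from 132 ± 8.29 to 47.7 ± 10.3 FPKM. In the smooth muscle and myofibroblast list 4 rose and 11 fell of 16, with a median of -0.68 (camera adjusted p = 0.0271, adjusted p = 0.554 with an estimated correlation). TAGLN fell from 1283 ± 59.3 to 222 ± 49.9 FPKM and ACTA2 fell from 283 ± 5.98 to 127 ± 11.5 FPKM, while SYNPO2 rose from 1.95 ± 0.283 to 12.02 ± 5.23 FPKM. This call was lost without GM replicate 3 (camera adjusted p = 0.0563), with an FPKM minimum of 5, on log2(FPKM + 0.1) and on quantile-normalized FPKM (camera adjusted p = 0.0883, 0.0699 and 0.321). Cholesterol synthesis genes were also lower (1 rose and 10 fell of 18, 1 and 9 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0357, adjusted p = 0.673 with an estimated correlation). EBP fell from 96.4 ± 8.96 to 19.9 ± 7.55 FPKM and PMVK fell from 73.8 ± 8.44 to 28.5 ± 3.83 FPKM, and the call was lost without GM replicate 1 or 2 (camera adjusted p = 0.0551 and 0.0614). It was lost as well with an FPKM minimum of 5, with PM and GM fitted alone, on log2(FPKM + 0.1) and on quantile-normalized FPKM (camera adjusted p = 0.118, 0.0586, 0.0670 and 0.331).

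Epidermal markers were higher in GM (7 rose and 0 fell of 9), with a median of 1.75 (camera adjusted p = 0.0276, adjusted p = 0.554 with an estimated correlation). CDH1, the epithelial cadherin, rose from 5.18 ± 0.326 to 34.3 ± 16.1 FPKM and TP63 rose from 3.99 ± 0.481 to 14.8 ± 6.49 FPKM. The call was lost with an FPKM minimum of 5, on log2(FPKM + 0.1) and on quantile-normalized FPKM (camera adjusted p = 0.309, 0.183 and 0.269). Haemoglobin genes stood out among the rises. HBAA had 3 reads over the PM libraries and 1054 over the GM libraries, a ratio of 226 with a counting interval of 77.2 to 1099. HBAD had 0 and 319 reads and was at least 68.5-fold higher in GM against a floor of 3 reads over the group. All 3 PM reads were in PM replicate 3, so without that library HBAA had 0 reads in PM. GM replicates 1, 2 and 3 had 227, 131 and 696 HBAA reads and 41, 53 and 225 HBAD reads. Without GM replicate 3 the HBAA ratio was 119 and HBAD was at least 31.4-fold higher. The erythroid list was not called (6 rose and 2 fell of 10, camera adjusted p = 0.152). Other large rises were EGF (from 0.479 ± 0.0665 to 14.0 ± 7.63 FPKM), SLC16A6 (from 0.891 ± 0.269 to 17.1 ± 5.62 FPKM) and DMGDH (from 0.798 ± 0.0956 to 13.6 ± 5.92 FPKM). The largest falls included PSCA (from 48.4 ± 1.56 to 1.77 ± 1.64 FPKM), P2RY6 (from 22.004 ± 1.12 to 1.16 ± 0.703 FPKM) and COL8A1 (from 19.96 ± 0.626 to 1.19 ± 0.326 FPKM). The log2 fold change of PSCA was -6.00 without GM replicate 2, and that of P2RY6 was -5.04 without GM replicate 3.

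Cell cycle lists were not called in GM versus PM, though many members fell. In the mitosis list 1 rose and 19 fell of 40 (1 and 15 adjusted over the list alone, camera adjusted p = 0.103), and UBE2C fell from 317 ± 16.9 to 132 ± 34.5 FPKM. In the DNA replication list 2 rose and 20 fell of 37 (2 and 19 adjusted over the list alone, camera adjusted p = 0.0821), and E2F1 fell from 40.5 ± 1.96 to 15.8 ± 2.96 FPKM. The calls of these lists appeared without GM replicate 1 (camera adjusted p = 0.0304 and 0.0218) and without GM replicate 2 (camera adjusted p = 0.0116 and 0.0229). Without GM replicate 3 the medians moved from -0.44 to -0.23 and from -0.36 to -0.24 (camera adjusted p = 0.347 and 0.219). Both lists passed without the low-count filter (camera adjusted p = 0.00879 and 0.00756) and with the length trend removed (camera adjusted p = 0.0161 and 0.0150), and mitosis on log2(FPKM + 0.1) (camera adjusted p = 0.0478). None of the other lists passed (camera adjusted p = 0.0832 to 0.979). In the unfolded protein and integrated stress list 4 rose and 16 fell of 26, and in the immediate early list 15 rose and 5 fell of 27. The former passed without the low-count filter and with the length trend removed (camera adjusted p = 0.0101 and 0.0429), and the latter on quantile-normalized FPKM (camera adjusted p = 0.00906). In the list of cell cycle exit 9 rose and 9 fell of 21, with CDKN2A falling from 5.62 ± 0.955 to 0.348 ± 0.134 FPKM and CCND1 rising from 27.9 ± 2.89 to 84.2 ± 10.4 FPKM. The connective tissue matrix list held 12 rose and 11 fell of 32, the chondrocyte and tendon list 4 rose and 10 fell of 17, the adipocyte list 3 rose and 5 fell of 13, the endothelial list 6 rose and 4 fell of 13 and the neural and Schwann cell list 7 rose and 4 fell of 14. With an FPKM minimum of 5 the endothelial list passed and its median turned from 0.66 to -1.89 (camera adjusted p = 0.0394). For glycolysis 7 rose and 8 fell of 19, for muscle energy metabolism 8 rose and 8 fell of 21, for proteolysis 11 rose and 7 fell of 22, for growth factor signalling 13 rose and 14 fell of 37 and for Notch and satellite cell genes 6 rose and 8 fell of 21. CTGF and TGFB1 fell from 794 ± 15.3 to 189 ± 25.3 FPKM and from 544 ± 32.8 to 155 ± 7.84 FPKM, while the IGF receptor gene IGF1R rose from 4.54 ± 0.612 to 21.8 ± 1.09 FPKM.

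In all, 9777 of 14796 genes changed between GM and PM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), of which 4732 rose and 5045 fell. Rises outnumbered falls on log2(FPKM + 0.1) (5112 and 3941), with PM and GM fitted alone (4865 and 4482) and with the length trend removed (4916 and 4624), so the balance of directions depended on the scale and the fit. Changes of at least 2-fold numbered 2167 rises and 1758 falls. Where no separate count is given, the counts in each list were the same over all genes and adjusted over the list alone, except 37 and 4 adjusted over the list alone for sarcomere genes and 17 and 1 adjusted over the list alone for coupling genes. The PM tables list 25950 features each against 26591 in each GM and DM table, so a processing batch and the PM group cannot be told apart. With all 29 lists and 3 comparisons adjusted together, no list was called in any comparison once camera estimated the correlation between genes.

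The DM versus GM comparison asked which genes differed between cells after 4 days in differentiation medium and cells in growth medium. The labels give no time in growth medium and do not say whether DM cells came from GM cultures. Medium, serum and time in culture therefore cannot be told apart. Cell cycle genes fell. In the mitosis list 0 rose and 39 fell of 40, with a median of -2.30 (camera adjusted p = 5.69e-22, adjusted p = 0.554 with an estimated correlation). KIF11, a spindle motor, fell from 48.6 ± 15.9 to 6.42 ± 1.12 FPKM (log2 fold change -2.86, SE 0.24, edgeR adjusted p = 7.48e-06), MELK fell from 13.8 ± 4.63 to 2.01 ± 0.646 FPKM, DLGAP5 fell from 24.9 ± 7.88 to 4.00 ± 0.523 FPKM and RACGAP1 fell from 33.6 ± 11.8 to 5.38 ± 0.413 FPKM. In the DNA replication list 3 rose and 33 fell of 37, with a median of -1.56 (camera adjusted p = 3.63e-13, adjusted p = 0.554 with an estimated correlation). TK1 and RRM2, which supply deoxynucleotides, fell from 75.7 ± 22.5 to 10.5 ± 0.939 FPKM and from 80.9 ± 27.5 to 11.2 ± 0.984 FPKM. CDKN1A, the cyclin-dependent kinase inhibitor p21 (ENSGALG00000028318, chromosome 26, 1588453 to 1591609, plus strand), rose from 33.5 ± 7.59 to 111 ± 15.2 FPKM (log2 fold change 1.78, SE 0.17, edgeR adjusted p = 1.14e-05). CDKN2A rose from 0.348 ± 0.134 to 11.3 ± 1.84 FPKM and GAS2 rose from 4.72 ± 0.433 to 35.4 ± 4.18 FPKM, although the list of cell cycle exit was not called (7 rose and 8 fell of 21), and its median of -0.26 and mean of 0.34 differed in sign.

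Sarcomere genes were lower in DM than in GM. In this list 3 rose and 26 fell of 43, with a median of -0.87 (camera adjusted p = 1.30e-04, adjusted p = 0.786 with an estimated correlation). CSRP3, a Z-disc protein, fell from 79.3 ± 32.1 to 4.54 ± 1.40 FPKM (log2 fold change -4.07, SE 0.34, edgeR adjusted p = 1.17e-05). MYBPH fell from 124 ± 72.02 to 17.9 ± 0.956 FPKM, UNC45B, a myosin chaperone, fell from 54.96 ± 25.3 to 9.38 ± 0.27 FPKM and DES fell from 811 ± 407 to 142 ± 7.98 FPKM. MYBPC1 rose from 1.10 ± 1.05 to 7.26 ± 1.53 FPKM. GM replicate 3 weighed on these values: without it the sarcomere median was -0.47, and the log2 fold changes were -2.14 for MYBPH and 3.94 for MYBPC1. Neuromuscular junction genes also fell (2 rose and 11 fell of 20), with a median of -0.61 (camera adjusted p = 0.0276, adjusted p = 0.719 with an estimated correlation). AGRN fell from 12.4 ± 2.47 to 2.81 ± 0.44 FPKM and DMD fell from 19.2 ± 2.73 to 7.98 ± 0.888 FPKM. That call was lost without GM replicate 3 (camera adjusted p = 0.101). The coupling list was not called (1 rose and 11 fell of 20, camera adjusted p = 0.0832), and passed without GM replicate 1 or 2 (camera adjusted p = 0.0359 and 0.0258) and without the low-count filter (camera adjusted p = 0.0216). Without GM replicate 3 its median was -0.39 against -0.62 (camera adjusted p = 0.193). SRL fell from 143 ± 67.6 to 25.8 ± 3.29 FPKM and ASPH rose from 15.4 ± 4.36 to 43.0 ± 2.51 FPKM.

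Among myogenic regulators, 2 rose and 13 fell of 19 (2 and 14 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 6.84e-04, adjusted p = 0.554 with an estimated correlation). The median was -0.37 without GM replicate 3. MYF5 fell from 294 ± 94.7 to 37.0 ± 8.65 FPKM (log2 fold change -2.93, SE 0.25, edgeR adjusted p = 1.36e-05). MYF6 fell from 44.0 ± 10.4 to 10.95 ± 2.06 FPKM, MYOD1 fell from 254 ± 37.2 to 145 ± 11.2 FPKM, ID2 fell from 109.9 ± 16.9 to 28.6 ± 1.12 FPKM and PITX3 fell from 65.4 ± 4.68 to 20.4 ± 0.251 FPKM. MYOG was 367 ± 138 FPKM in GM and 299.9 ± 27.0 FPKM in DM (log2 fold change -0.24, SE 0.23, edgeR adjusted p = 0.393). Without GM replicate 3 its log2 fold change was 0.14. MEF2C was 92.7 ± 50.1 FPKM in GM and 49.5 ± 3.46 FPKM in DM (log2 fold change -0.86, edgeR adjusted p = 0.0520), and passed without GM replicate 1, 2 or 3 (edgeR adjusted p = 0.0251, 0.0169 and 0.0135), at -0.29 in the last case. TMEM8C was 86.8 ± 4.58 FPKM in DM (log2 fold change -0.40, edgeR adjusted p = 0.174) and passed without GM replicate 2 (edgeR adjusted p = 0.0338). Without GM replicate 3 its log2 fold change was -0.005 (edgeR adjusted p = 0.958). MSTN rose from 6.39 ± 1.64 to 12.8 ± 0.0554 FPKM. The fusion list was not called (6 rose and 7 fell of 23), with CAV3 falling from 149.7 ± 81.3 to 24.0 ± 1.30 FPKM and DYSF, a membrane repair protein, rising from 11.4 ± 1.37 to 28.3 ± 1.54 FPKM.

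Genes of connective tissue and smooth muscle were higher in DM. In the list of matrix and fibroblast markers 21 rose and 2 fell of 32, with a median of 0.79 (camera adjusted p = 4.97e-07, adjusted p = 0.554 with an estimated correlation). SFRP2, a secreted Wnt modulator, rose from 2.53 ± 0.873 to 131 ± 31.2 FPKM (log2 fold change 5.76, SE 0.25, edgeR adjusted p = 1.24e-07), DPT rose from 1.84 ± 0.505 to 80.6 ± 2.77 FPKM, FBLN5 rose from 0.463 ± 0.108 to 9.96 ± 2.43 FPKM and the proteoglycan gene LUM rose from 25.1 ± 6.10 to 286 ± 40.2 FPKM. In the smooth muscle and myofibroblast list 10 rose and 4 fell of 16, with a median of 0.80 (camera adjusted p = 1.30e-04, adjusted p = 0.453 with an estimated correlation). ACTA2, smooth muscle actin (ENSGALG00000006343, chromosome 6, 19231810 to 19241381, minus strand), rose from 127 ± 11.5 to 1926 ± 109 FPKM (log2 fold change 3.98, SE 0.09, edgeR adjusted p = 4.48e-10), MYLK rose from 4.33 ± 0.394 to 26.5 ± 0.676 FPKM and TAGLN rose from 222 ± 49.9 to 1179 ± 193 FPKM. The smooth muscle call was lost on log2(FPKM + 0.1) and on quantile-normalized FPKM (camera adjusted p = 0.0505 and 0.104). In the chondrocyte and tendon list SCX rose from 0.403 ± 0.139 to 15.7 ± 1.67 FPKM and MKX rose from 3.95 ± 1.48 to 23.7 ± 1.07 FPKM. THBS4 fell from 13.4 ± 1.41 to 0.383 ± 0.0873 FPKM and SPP1, osteopontin, fell from 1139 ± 151 to 44.1 ± 1.68 FPKM. That list was not called (6 rose and 6 fell of 17). OSTN, musclin, showed the largest rise in DM versus GM among the genes named by the fixed rule, from 0.419 ± 0.0968 to 40.8 ± 6.12 FPKM (log2 fold change 6.63, SE 0.28, edgeR adjusted p = 1.11e-08). SPON2 rose from 1.39 ± 0.251 to 85.2 ± 13.1 FPKM and ABHD8 rose from 0.445 ± 0.0708 to 17.5 ± 2.59 FPKM, while CPM fell from 90.3 ± 17.1 to 2.19 ± 0.323 FPKM and TPPP3 fell from 13.2 ± 1.61 to 0.528 ± 0.253 FPKM.

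Stress genes divided. In the unfolded protein and integrated stress list 16 rose and 4 fell of 26, with a median of 0.46 (camera adjusted p = 3.69e-08, adjusted p = 0.453 with an estimated correlation). The largest changes were in CHAC1, a glutathione-degrading enzyme, which rose from 8.31 ± 1.12 to 184 ± 36.9 FPKM (log2 fold change 4.53, SE 0.16, edgeR adjusted p = 8.93e-09), and in the serine synthesis genes PHGDH (ENSGALG00000002988, chromosome 8, 4264703 to 4268005, minus strand) and PSPH, which rose from 70.8 ± 21.8 to 1476 ± 119.9 FPKM and from 8.87 ± 0.32 to 62.7 ± 3.62 FPKM. DDIT4 rose from 174 ± 39.6 to 995 ± 187 FPKM. Immediate early genes fell (2 rose and 22 fell of 27), with a median of -1.06 (camera adjusted p = 2.91e-08, adjusted p = 0.554 with an estimated correlation). FOS fell from 31.6 ± 6.57 to 6.10 ± 0.866 FPKM, EGR1 fell from 227 ± 35.3 to 48.0 ± 4.09 FPKM and NR4A3 fell from 17.1 ± 5.17 to 2.02 ± 0.303 FPKM. Ribosomal protein genes were higher (55 rose and 0 fell of 58, 56 and 0 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 2.15e-10, adjusted p = 0.570 with an estimated correlation), and RPS27 rose from 1404 ± 149 to 3128 ± 131 FPKM. Interferon response genes were higher as well (12 rose and 2 fell of 20, 13 and 2 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.0256, adjusted p = 0.755 with an estimated correlation), and B2M rose from 47.7 ± 10.3 to 169 ± 3.71 FPKM. The interferon call was lost without GM replicate 3 or DM replicate 1 (camera adjusted p = 0.0577 and 0.0619). Cholesterol synthesis genes fell (0 rose and 16 fell of 18, 1 and 16 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 4.34e-12, adjusted p = 0.453 with an estimated correlation). INSIG1 fell from 88.4 ± 5.98 to 18.4 ± 1.27 FPKM, LSS fell from 70.1 ± 0.892 to 21.0 ± 0.902 FPKM and SQLE fell from 77.3 ± 7.51 to 23.8 ± 1.08 FPKM.

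The other lists were not called in DM versus GM. Epidermal markers held 0 rose and 7 fell of 9 (camera adjusted p = 0.0573), with TP63 falling from 14.8 ± 6.49 to 2.94 ± 0.153 FPKM, and passed without GM replicate 1 or 2 (camera adjusted p = 0.0447 and 0.0145), without the low-count filter and with DM and GM fitted alone (camera adjusted p = 0.0142 and 0.0499). For the erythroid list 1 rose and 7 fell of 10 (2 and 7 adjusted over the list alone, camera adjusted p = 0.0638), and it passed without GM replicate 2 or DM replicate 3 (camera adjusted p = 0.0419 and 0.0383), without the low-count filter and with DM and GM fitted alone (camera adjusted p = 0.0268 and 0.0482). HBAA had 1 read over the DM libraries, so that GM lay 920.0 times higher with a counting interval of 165 to 36374, and HBAD also had 1 read in DM. Without GM replicate 3 the HBAA ratio was 486 (86.6 to 19241). For macrophage and leukocyte markers 6 rose and 2 fell of 22, with CTSS rising from 21.9 ± 9.24 to 50.9 ± 3.46 FPKM, and the list passed without GM replicate 3 (camera adjusted p = 7.63e-04). The camera adjusted p of this and the lists that follow was 0.205 to 0.998. Nuclear oxidative phosphorylation genes held 15 rose and 9 fell of 44, and mitochondrially encoded genes 1 rose and 4 fell of 13. For mitochondrially encoded genes the list passed on quantile-normalized FPKM (camera adjusted p = 0.0212). For endothelial markers 4 rose and 5 fell of 13, with a median of -0.58, and 2.31 with an FPKM minimum of 5, where the list passed (camera adjusted p = 0.0122). For adipocyte markers 4 rose and 4 fell of 13, for neural and Schwann cell markers 3 rose and 6 fell of 14, for Notch and satellite cell genes 5 rose and 8 fell of 21 (6 and 8 adjusted over the list alone) and for growth factor signalling 11 rose and 20 fell of 37. For glycolysis 10 rose and 5 fell of 19, for muscle energy metabolism 11 rose and 5 fell of 21 and for proteolysis 12 rose and 5 fell of 22. PPARG rose from 9.41 ± 0.935 to 32.4 ± 2.17 FPKM, HGF rose from 3.36 ± 0.695 to 11.6 ± 2.10 FPKM, its receptor gene MET fell from 20.6 ± 4.88 to 5.30 ± 0.258 FPKM, and ENO3, the muscle enolase, rose from 3.98 ± 1.21 to 26.5 ± 1.53 FPKM.

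**Figure D4:**
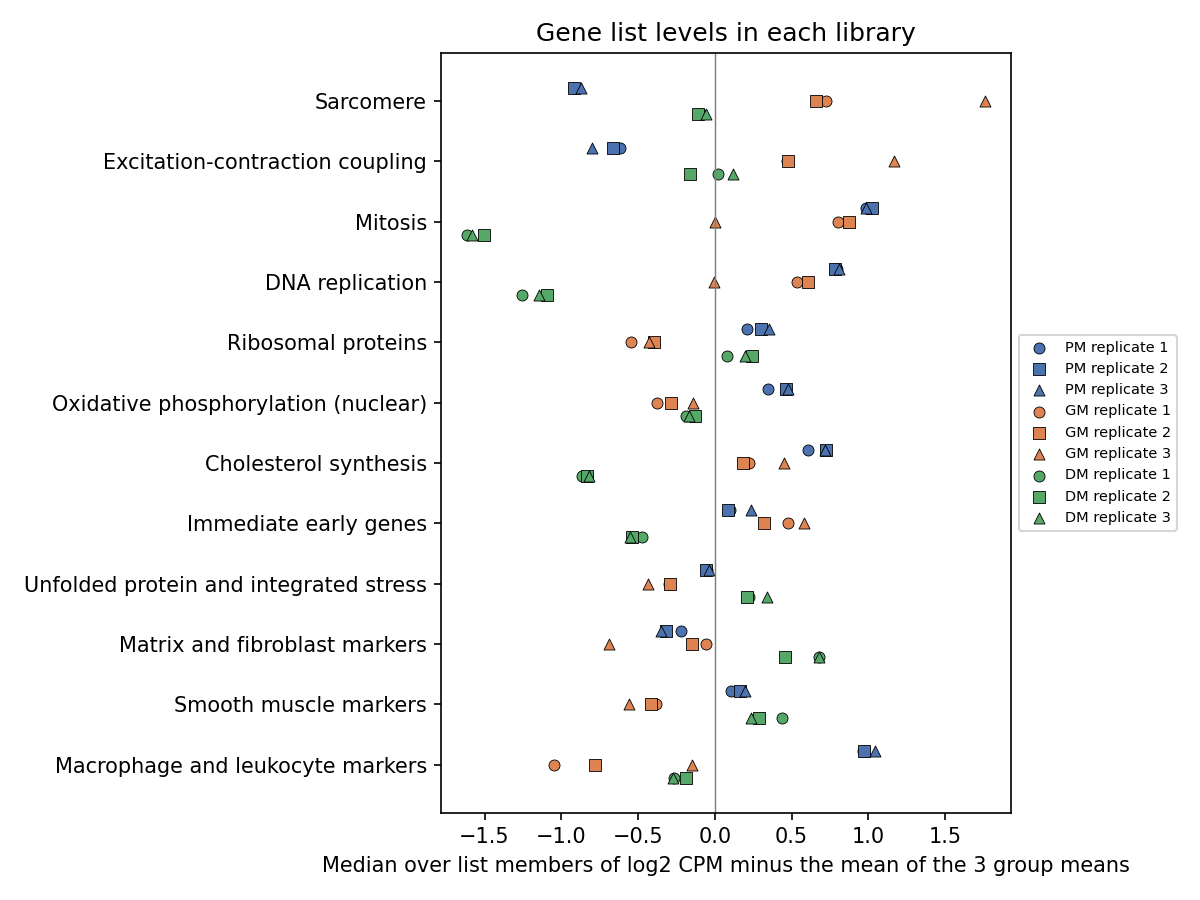
Median over the members of 12 gene lists (rows) of log2 CPM minus the mean of the 3 group means (horizontal axis), 1 point per library. Sarcomere genes lie highest in GM and mitosis genes lowest in DM, where the list stands at -1.61, -1.50 and -1.58, and GM replicate 3 lies apart from the other GM libraries in both.

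Between DM and GM, 9038 of 14796 genes changed (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 4560 of them upward and 4478 downward. At least 2-fold changes numbered 1874 rises and 1643 falls. Counts adjusted over the list alone differed only where given. GM replicates spread more widely than those of PM or DM, and without GM replicate 3 the list medians above for sarcomere genes and myogenic regulators moved by more than 1.5 times.

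The DM versus PM comparison set the differentiated cells against cells just after plating. GM libraries enter it only through the normalisation and the spread shared by all 9 samples. A call gained or lost without a GM library therefore reflects these and not PM or DM levels. Cell cycle genes were lower in DM. In the mitosis list 0 rose and 40 fell of 40, with a median of -2.46 (camera adjusted p = 5.96e-25, adjusted p = 0.554 with an estimated correlation). UBE2C fell from 317 ± 16.9 to 24.7 ± 3.20 FPKM (log2 fold change -3.77, SE 0.19, edgeR adjusted p = 1.06e-07), the mitotic kinase gene CDK1 fell from 218 ± 11.1 to 24.6 ± 1.43 FPKM and BIRC5 fell from 78.1 ± 4.06 to 9.10 ± 1.02 FPKM. In the DNA replication list 1 rose and 33 fell of 37 (1 and 34 adjusted over the list alone), with a median of -2.004 (camera adjusted p = 5.34e-17, adjusted p = 0.554 with an estimated correlation), and MCM3, part of the replicative helicase, fell from 54.1 ± 0.0705 to 7.54 ± 0.813 FPKM. CDKN1A rose from 38.4 ± 1.92 to 111 ± 15.2 FPKM and CCNG1 rose from 103 ± 0.849 to 328 ± 18.2 FPKM, in a list of cell cycle exit that was not called (10 rose and 9 fell of 21, 11 and 9 adjusted over the list alone).

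Sarcomere genes were higher in DM than in PM (24 rose and 7 fell of 43, 25 and 7 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 0.0411, adjusted p = 0.875 with an estimated correlation). MYBPC1 rose from 0.122 ± 0.0319 to 7.26 ± 1.53 FPKM (log2 fold change 5.81, SE 0.76, edgeR adjusted p = 2.07e-04), MYOM2 rose from 1.35 ± 0.259 to 23.3 ± 3.26 FPKM, MYOZ1 rose from 3.53 ± 0.393 to 27.2 ± 0.927 FPKM and MYBPC3 rose from 4.78 ± 0.548 to 33.1 ± 2.85 FPKM. DES was 155 ± 3.66 FPKM in PM and 142 ± 7.98 FPKM in DM (edgeR adjusted p = 0.563) and passed without GM replicate 3 at a log2 fold change of -0.21 (edgeR adjusted p = 0.0161). The sarcomere call was lost without PM replicate 1 or DM replicate 1 (camera adjusted p = 0.0669 and 0.0617), with DESeq2 size factors, with an FPKM minimum of 5 and on log2(FPKM + 0.1) (camera adjusted p = 0.0501, 0.0598 and 0.0590). The coupling list was not called (10 rose and 0 fell of 20, camera adjusted p = 0.0573). It passed without GM replicate 1, 2 or 3 or DM replicate 2 (camera adjusted p = 0.0417, 0.0339, 0.00126 and 0.0477), and without the low-count filter, with DM and PM fitted alone, on log2(FPKM + 0.1) and on quantile-normalized FPKM (camera adjusted p = 0.0101, 0.00196, 0.0347 and 0.0444). CASQ2, a calcium store protein, rose from 17.7 ± 1.10 to 62.3 ± 4.32 FPKM and TRDN rose from 1.51 ± 0.0937 to 7.90 ± 1.68 FPKM. The neuromuscular junction list (12 rose and 4 fell of 20, 12 and 5 adjusted over the list alone) and the fusion list (8 rose and 5 fell of 23, 7 and 4 adjusted over the list alone) were not called either.

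Myogenic regulators divided by gene, and 9 rose and 10 fell of 19, with a median of -0.30 (camera adjusted p = 0.0195, adjusted p = 0.559 with an estimated correlation). MYF5 fell from 406 ± 22.2 to 37.0 ± 8.65 FPKM (log2 fold change -3.55, SE 0.26, edgeR adjusted p = 3.79e-06), MYF6 fell from 102 ± 3.89 to 10.95 ± 2.06 FPKM, MYOD1 fell from 332 ± 11.7 to 145 ± 11.2 FPKM, ID2 fell from 173 ± 1.28 to 28.6 ± 1.12 FPKM and ID4 fell from 968 ± 62.0 to 141 ± 10.9 FPKM. MEF2C rose from 9.10 ± 1.19 to 49.5 ± 3.46 FPKM and MSTN rose from 3.73 ± 0.853 to 12.8 ± 0.0554 FPKM. MYOG rose from 177 ± 8.53 to 299.9 ± 27.0 FPKM (log2 fold change 0.67, SE 0.23, edgeR adjusted p = 0.0311), a call lost without PM replicate 1, 2 or 3 or DM replicate 1 or 2 (edgeR adjusted p = 0.0879, 0.0576, 0.0631, 0.0551 and 0.0797) and without the low-count filter (edgeR adjusted p = 0.0717). TMEM8C did not pass (edgeR adjusted p = 0.496), and did without GM replicate 3 (edgeR adjusted p = 0.0192). The list call was lost without GM replicate 3, with DM and PM fitted alone and on log2(FPKM + 0.1) (camera adjusted p = 0.102, 0.0757 and 0.307). It was also lost with an FPKM minimum of 5 and on quantile-normalized FPKM, where the medians were 0.20 and 0.07 (camera adjusted p = 0.118 and 0.588).

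Matrix genes were higher in DM (22 rose and 3 fell of 32, 22 and 4 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 9.04e-07, adjusted p = 0.554 with an estimated correlation). DPT rose from 0.835 ± 0.229 to 80.6 ± 2.77 FPKM (log2 fold change 6.46, SE 0.21, edgeR adjusted p = 2.08e-09), FBLN1 rose from 11.98 ± 1.64 to 164 ± 13.6 FPKM and OGN, osteoglycin, rose from 0.858 ± 0.515 to 12.6 ± 5.10 FPKM. The smooth muscle list was not called (6 rose and 4 fell of 16), with MYH11 rising from 1.38 ± 0.169 to 6.18 ± 0.429 FPKM and TGFBI falling from 1045 ± 15.3 to 191 ± 16.8 FPKM. Macrophage and leukocyte markers were lower (2 rose and 17 fell of 22), with a median of -1.23 (camera adjusted p = 8.59e-04, adjusted p = 0.605 with an estimated correlation), and C1QB fell from 231 ± 3.02 to 26.9 ± 3.44 FPKM and IL8 fell from 25.5 ± 1.04 to 2.80 ± 1.53 FPKM. Cholesterol synthesis genes fell (0 rose and 18 fell of 18), with a median of -1.64 (camera adjusted p = 1.76e-17, adjusted p = 0.453 with an estimated correlation), and HSD17B7 fell from 57.4 ± 3.20 to 15.7 ± 0.622 FPKM. Nuclear oxidative phosphorylation genes fell (0 rose and 40 fell of 44, 0 and 42 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 1.97e-08, adjusted p = 0.562 with an estimated correlation), and CYCS, cytochrome c, fell from 236 ± 0.917 to 98.8 ± 3.55 FPKM. Their median was -0.40 with the gene length trend removed. Immediate early genes fell (4 rose and 17 fell of 27, 4 and 20 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 3.68e-04, adjusted p = 0.570 with an estimated correlation), and KLF2 fell from 62.4 ± 5.15 to 17.5 ± 3.30 FPKM. In the unfolded protein and integrated stress list 13 rose and 10 fell of 26 (14 and 10 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00161, adjusted p = 0.554 with an estimated correlation). PHGDH rose from 36.0 ± 2.20 to 1476 ± 119.9 FPKM (log2 fold change 5.26, SE 0.23, edgeR adjusted p = 8.83e-08), and PSAT1, of the same serine pathway, rose from 22.2 ± 0.385 to 118 ± 4.61 FPKM. With the length trend removed the stress list had a median of 0.20, and its call was lost on log2(FPKM + 0.1) (camera adjusted p = 0.161).

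The remaining lists were not called in DM versus PM (camera adjusted p = 0.257 to 0.866, and 0.056 for chondrocyte and tendon genes). For ribosomal genes 6 rose and 20 fell of 58 (6 and 19 adjusted over the list alone), for interferon response 3 rose and 9 fell of 20, for mitochondrially encoded genes 4 rose and 1 fell of 13, for epidermal markers 4 rose and 2 fell of 9 and for erythroid markers 2 rose and 2 fell of 10. In the chondrocyte and tendon list 7 rose and 10 fell of 17 (camera adjusted p = 0.056), and it passed without PM replicate 1 or 3 or GM replicate 2 (camera adjusted p = 0.0284, 0.0302 and 0.0339) and with the length trend removed (camera adjusted p = 0.0413). For endothelial markers 3 rose and 4 fell of 13 (2 and 4 adjusted over the list alone), for adipocyte markers 3 rose and 4 fell of 13 and for neural and Schwann cell markers 3 rose and 5 fell of 14. For glycolysis 8 rose and 6 fell of 19, for muscle energy metabolism 11 rose and 4 fell of 21, for proteolysis 10 rose and 7 fell of 22, for growth factor signalling 18 rose and 15 fell of 37 and for Notch and satellite cell genes 4 rose and 10 fell of 21. ADIPOQ fell from 7.11 ± 0.518 to 0.477 ± 0.165 FPKM, IGFBP2 fell from 183 ± 6.75 to 22.9 ± 4.19 FPKM and FGFR4 fell from 68.4 ± 4.25 to 15.8 ± 2.32 FPKM. Besides SPP1, which fell from 2011 ± 94.2 to 44.1 ± 1.68 FPKM, the largest falls included WISP2 (from 46.2 ± 4.34 to 1.15 ± 0.411 FPKM) and MLANA (from 224 ± 13.3 to 6.64 ± 1.20 FPKM).

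Between DM and PM, 9788 of 14796 genes changed (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 4951 rising and 4837 falling. Changes of at least 2-fold numbered 2359 rises and 1793 falls. Fold changes were higher for longer genes here too, and the PM tables differ from the DM tables as they do from the GM tables.

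With the 3 groups ordered PM, GM and DM, genes more often changed in opposite directions in the 2 steps than in the same one. The labels do not state that these separate libraries form a time course. Called in both steps, 2295 genes rose from PM to GM and fell from GM to DM, as DES did, and 2518 fell and then rose, as ACTA2 and TAGLN did. Genes that rose and then fell were the more numerous of these classes on log2(FPKM + 0.1) (2554 against 2006), on quantile-normalized FPKM (2478 against 2276), with the length trend removed (2429 against 2317) and with the groups of each step fitted alone (2311 against 2254). MSTN rose in both steps and MYF5 and MYOD1 fell in both, with GM versus PM calls that were lost under some of the alternatives given above. They were among 681 genes that rose and 853 that fell in both steps. Independent lists of these sizes would share 1432, 1555, 1458 and 1527 genes in the same order. In 20 simulations of unchanged groups that shared the GM libraries, the largest class held 1 gene, which bears only on calls made by chance and not on the direction of real changes. Across genes, which are not independent replicates, the 2 steps correlated at -0.35 against -0.47 in the simulations. Their covariance was -0.46 against -0.03, a difference of -0.43. The 3 GM libraries enter both steps and cannot be split into groups of at least 2, so part of the excess of opposite directions may come from them.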

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

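Tests in this part were chosen after the results were seen, apart from the count of other splits of the samples, which was written before. The prediction on gene length for W-linked genes was also written before. Its fit with the length trend removed was added after seeing the data. Unannotated features in the GM and DM tables lay outside the main measurement and were tested for DM versus GM only. Of 1710 such features, 1446 had enough reads and 786 changed between DM and GM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 404 upward and 382 downward. At an unadjusted p below 0.05 there were 872. The main test of DM versus GM called 9038 of 14796 genes, or 61.1%, so these features were not called more often than genes.

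The numbers of changed genes were set against other splits of the same 6 libraries. For GM versus PM, 1 of the 10 splits, the real one, gave as many calls, 9347 against at most 0 in the others. For DM versus GM it was again 1 of 10, with 8716 calls against at most 0. For DM versus PM it was 1 of 10, with 10316 calls against at most 8. With 10 splits the share can never fall below 0.1, so the splits are too few to test chance at 0.05. The other splits also put libraries of both groups on each side, so the group difference widens their spread and holds their calls down. Their few calls therefore say nothing about chance.

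Genes on the W chromosome, which only female birds carry, were higher in GM and DM than in PM. Of 28 tested, 21 rose and 0 fell in GM versus PM with a median log2 fold change of 1.24, the median in DM versus PM was 1.25, and that in DM versus GM was 0.02. W-linked reads took 156 to 171 CPM in PM, 364 to 387 in GM and 393 to 416 in DM. The gene length trend argues against itself as the whole cause, since the median was 1.27 with the trend removed. A smaller share of female cells in PM may explain the pattern and would put Z-linked genes lower in GM, where they lay -0.0685 from autosomal genes (permutation p = 0.0884 over 655 Z-linked genes, two-sided), which does not decide it, and the separate tabulation of PM also stays open.

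Sarcomere genes were lower in DM than in GM, with a median log2 fold change of -0.87. An exchange of GM and DM labels is argued against by the mitosis list, whose median was -2.30 in the libraries labelled DM. GM replicate 3 alone does not account for it, since without that library 27 of 43 genes fell and 9 rose, and the median was -0.47 (camera adjusted p = 6.32e-06 at the preset correlation, while over all libraries the list had adjusted p = 0.786 with an estimated correlation), although the size of the change depends on it. A lower share of muscle cells in DM need not raise every other cell type, so the marker lists cannot exclude it. If all other types gained alike, their lists would lie above 0. Of the 9 lists, 5 had a median below 0, with epidermal markers at -1.69 (0 rose, 7 fell). With an FPKM minimum of 5, the endothelial, chondrocyte and tendon, and neural medians among these were 2.31, 0.44 and 0.41. Matrix markers lay at 0.79 (21 rose, 2 fell) and smooth muscle markers at 0.80 (10 rose, 4 fell), so a muscle share lowered by growth of these types alone stays open. A change within the muscle cells between the media, which the design names, stays open and was not tested apart from these.

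GM replicate 3 lay apart from the other GM libraries, with the sarcomere list 1.07 higher and the mitosis list 0.85 lower on the log2 scale. An exchange with a DM library is argued against by 3442 genes that separate DM from GM replicates 1 and 2, on which it stood at a median of 0.0239 of the way to DM (quartiles -0.20 and 0.27). A larger share of muscle-lineage cells could come at the cost of only some other cell types, so the marker lists cannot exclude it. If all other types fell alike, their lists would lie lower. By the median difference over members, 3 of the 9 lists lay higher by more than GM replicates 1 and 2 differed (macrophage 0.86, epidermal 0.70, erythroid 0.35). Another 3 lay lower (matrix -0.46, neural -0.23, chondrocyte and tendon -0.19) and 3 within that difference, which rests on these libraries alone. The erythroid medians per library were 1.04, 0.86 and 1.09 in GM replicates 1, 2 and 3, so its place depends on the measure. A candidate explanation that stays open is that more cells had left the cell cycle and begun to differentiate in that library. Excitation-contraction coupling genes lay 0.76 higher and DNA replication genes at -0.63, against differences of 0.08 and 0.03 between the other GM libraries. Across the groups these lists moved with the sarcomere and mitosis lists that define the pattern, so they give no independent evidence. No group label bears on this explanation.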

How the results depend on the processing

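Counts of changed genes stayed within 1.5 times of the main counts under every alternative run except the 2-fold minimum, which left 3925 genes for GM versus PM, 3517 for DM versus GM and 4152 for DM versus PM, by its own construction. Leaving out each replicate in turn gave 8838 to 9813, 8052 to 9139 and 8875 to 10426 calls, and 9 to 12, 11 to 15 and 9 to 12 called lists. With an estimated correlation camera called 0 lists in each comparison, against 11, 12 and 10 with the preset one. DESeq2 gives no camera value. On log2(FPKM + 1) the cholesterol, epidermal and smooth muscle calls in GM versus PM were lost (camera adjusted p = 0.0709, 0.193 and 0.0651). In DM versus PM the myogenic regulator, sarcomere and unfolded protein calls were lost there (camera adjusted p = 0.318, 0.0597 and 0.145). Mitosis in GM versus PM and coupling in DM versus PM newly passed (camera adjusted p = 0.0471 and 0.0447). The replicate numbers did not pair the samples: correlations of same-numbered libraries ran from -0.11 to 0.10, and 3 of 9 libraries correlated best with their own number. With the replicate block there were 9537, 8755 and 9580 calls and 12, 14 and 12 lists, newly the erythroid list in GM versus PM, the epidermal and erythroid lists in DM versus GM, and the chondrocyte and coupling lists in DM versus PM, and trajectory classes of 623, 2194, 2449 and 802 genes against 681, 2295, 2518 and 853.

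Of 7388 values for named genes under alternatives, 7292 kept their direction and side of the threshold. Of the rest, 66 no longer passed, 26 newly passed and 4 changed sign. Of 1740 list values, 1618 kept their side of the threshold, a count that ignores the test direction of lists not called before or after. Another 76 no longer passed, 45 newly passed and 1 changed the direction of its test with a call before or after. These changes of direction included MT-ND3 in DM versus GM (-0.0162) and DES in DM versus PM (0.13) on quantile-normalized FPKM. TFRC in GM versus PM (-0.0356) changed with the length trend removed, an alternative chosen after seeing the data. MYOG in DM versus GM, which did not pass, changed as well (0.14 without GM replicate 3, and -0.41 to 0.14 over all replicates left out). The last was the endothelial list in DM versus GM (2.31, camera adjusted p = 0.0122) among genes with an FPKM of at least 5 in 3 samples, where fewer members are tested. The cause was not tested for the other 4. Apart from the test, 66 of 1653 list medians changed sign, 4 of them with a call before or after: the endothelial list in GM versus PM (-1.89) and DM versus GM at an FPKM of at least 5, and myogenic regulators in DM versus PM (0.20 there and 0.07 on quantile-normalized FPKM). Shallower PM libraries and the wide GM spread limit what small changes can show.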

Other observations

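MLANA, a melanocyte antigen gene, was abundant in PM but other pigment cell genes, chosen after its value was seen, were not. It stood at 224 ± 13.3 FPKM in PM, 16.8 ± 10.1 in GM and 6.64 ± 1.20 in DM. DCT, an enzyme of melanin synthesis, stood at 1.27 ± 0.0501 FPKM in PM, 0.0452 ± 0.0159 in GM and 0 in DM. PMEL, a melanosome protein, was at 0.684 ± 0.171, 0.317 ± 0.062 and 0.305 ± 0.135 FPKM, and MITF, which other cells also express, at 9.42 ± 0.665, 8.82 ± 0.868 and 11.3 ± 0.492 FPKM.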
